A study of Mus musculus with 4 samples.

How the data were processed

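RNA sequencing libraries of 2 clonal mouse lines of progenitors of interstitial cells of Cajal were used, 2 per line. Per the labels' protocols, total RNA was extracted with a Qiagen miRNeasy kit, and libraries were made with an Illumina TruSeq mRNA kit and sequenced on an Illumina HiSeq instrument. Such a kit does not mark strand, so reads of a gene and of a gene overlapping it on the other strand could not be told apart. Reads were aligned and counted with tools that include TopHat2 2.0.6, Bowtie and HTSeq on the mouse build mm10, per the submitters' processing notes. The annotation used for counting is not given in the sources used here.

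The authors deposited raw counts per gene for each library, per the file headers, with 23358 gene rows on 21 chromosomes in each table. All deposited counts were even (0 odd values over the 4 libraries), so 1 sequenced fragment was taken as 2 counts, and floors and intervals were computed on fragments. The authors also deposited RPKM values, which relate counts to coding length and to the number of reads of the library, per the file headers. For genes above 200 counts these equalled the count divided by the length and by 1 fixed number of reads per library, namely 50468212 and 59036269 for 2xSCS2F10 and 62928743 and 61554553 for 2xSCS70, which was larger than the total in genes. In the tables of replicate 1, 25 gene names had been turned into dates and were restored from the other tables, and 69 rows shared a name with another row, 9 of them under Epb4, and were kept apart by position. The 13 members of a mitochondrial list were not analysed here. Coordinates are 1-based, as in the deposited tables, on mm10. Of the symbols, 20762 matched a RefSeq symbol of the reference table, which was used for names only.

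Libraries held 20159986 fragments in genes for 2xSCS2F10 replicate 1, 22549451 for its replicate 2, 24485632 for 2xSCS70 replicate 1 and 22368504 for its replicate 2. A floor of 3 fragments corresponded to 0.154 and 0.157 CPM in 2xSCS2F10 and 0.109 and 0.123 CPM in 2xSCS70. A gene at 0 counts in both libraries of a line was compared with that floor per library, and a gene with 1 to 3 fragments in a line was given as a ratio with an exact 95% interval.

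Samples were grouped by line from the labels. The lines were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test on the counts as deposited, with TMM scaling and the filterByExpr filter, which left 14496 genes tested and 8862 untested. Changes are 2xSCS70 minus 2xSCS2F10, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM were scaled with the TMM factors, with a prior count of 2 on the log2 scale. Median differences of lists and chromosomes between single libraries were taken on log2 CPM with a small constant added instead. The SE given with an edgeR change is the absolute log2 fold change divided by the square root of the F statistic of its test. The common biological coefficient of variation was 20.4%. Gene lists and chromosomes were tested with limma 3.58.1 by camera, which asks whether the members of a set moved more than other genes, at a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. Of 12 lists called with the preset correlation (4 higher and 8 lower), 0 were called with the estimated one, and of 8 chromosomes 0. At an unadjusted p under 0.05 with the estimated correlation the count of lists was 0 and that of chromosomes 2. Replicate numbers were compared with the line as a covariate. Before the data were examined, 31 gene lists with 682 members, of which 669 had a row, were fixed, together with the tests, the alternatives and the rule for the genes named. That rule took the 10 genes with the largest change each way among called genes with a mean of at least 10 CPM and no overlap between the lines, 12 genes of interest whatever their values, up to 4 called members of each list by adjusted p (or, where none was called, the 2 most abundant), the 5 largest each way between replicate numbers, and the 5 most abundant genes of each line. The test was checked on simulated counts drawn from the means of the real libraries, with the same spread for all genes and both lines.

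The alternatives were the replicate number as a block, RLE and upper quartile scaling, no filter, a filter at a mean of 5 CPM, each library left out, DESeq2 1.42.0, limma-voom, limma on log2(RPKM + 1) and log2(RPKM + 0.1), a test against a 1.5-fold change, the estimated correlation, fry in place of camera, and limits of 0.5 and 2 RPKM for detection. Where a library was left out, the lone library was taken to vary like the other line. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads of the large T antigen transgene were not analysed here, and 1 gene that the rule would name is not reported here.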

Results

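Transcriptomes were measured by sequencing of polyadenylated RNA in 2 clonal mouse cell lines derived from progenitors of the interstitial cells of Cajal, the pacemaker cells of gut muscle. The line 2xSCS2F10 came from the muscle layers of the stomach of C57BL/6J mice and was grown at 37 °C with 5% chick embryo extract. The line 2xSCS70 came from the same tissue of mice that carry a temperature-sensitive SV40 large T antigen under the interferon-inducible H-2Kb promoter, and was grown at 39.5 °C without interferon gamma. Each line was represented by 2 libraries, so that line, strain, temperature and medium changed together. The libraries held 40319972 and 45098902 counts in genes for 2xSCS2F10 and 48971264 and 44737008 for 2xSCS70, in the order of replicates 1 and 2. Values are given below as mean ± SD (n = 2 libraries per line) in CPM, counts scaled to the size of the library, unless another unit is named. The labels did not say that the libraries came from separate cultures, so the p-values measured only the spread between these libraries, which may be technical.

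The 2 libraries of 2xSCS70 resembled each other more closely than those of 2xSCS2F10. Across 23358 gene rows, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.999 within 2xSCS70, 0.990 within 2xSCS2F10, and between 0.943 and 0.953 for the pairs of different lines. A difference of more than 2-fold between replicates was seen for 394 tested genes (2.72%) in 2xSCS70 and for 1791 (12.4%) in 2xSCS2F10. Both pairs differed by more than sampling noise, with a chi-square per degree of freedom of 44.7 and 106, so neither pair was treated as 1 library deposited again. The first principal component separated the lines and held 90.8% of the variance.

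The most abundant transcripts of both lines were those of connective tissue, the cytoskeleton and the ribosome. In 2xSCS2F10 the genes after Rn45s (7974 ± 4032 RPKM) and Lars2 (2850 ± 1900 RPKM) were Col1a2, a chain of type I collagen (1987 ± 520 RPKM), Sparc, a collagen-binding matrix protein (1849 ± 198 RPKM), and Col1a1, the other type I collagen chain (1812 ± 28.8 RPKM). In 2xSCS70 they were the translation factor Eef1a1 (1573 ± 73.8 RPKM), cytoplasmic actin Actb (1085 ± 36.5 RPKM) and Col1a1 (1069 ± 257 RPKM), after Rn45s (5168 ± 3123 RPKM) and Lars2 (1811 ± 1115 RPKM). Col1a2 was 13.6-fold lower in 2xSCS70 (log2 fold change -3.76, SE 0.37, edgeR quasi-likelihood adjusted p = 0.00274), and Sparc was 2.11-fold (adjusted p = 0.023) and Col1a1 2.02-fold lower (adjusted p = 0.0361). Rn45s, ribosomal RNA left after selection of polyadenylated RNA, took 3.74% and 8.27% of the counts of 2xSCS2F10 and 2.22% and 5.92% of those of 2xSCS70, and reads of Lars2 may be shared with it. At 1 RPKM or more in both libraries, 10382 genes were detected in 2xSCS2F10, 10817 in 2xSCS70 and 9804 in both. The calls of Col1a2, Sparc and Col1a1 ended without 2xSCS70 replicate 1 (adjusted p 0.0823, 0.247 and 0.28) and without replicate 2 (0.0859, 0.273 and 0.419). Those of Sparc and Col1a1 also ended on log2(RPKM + 1) values (0.195 and 0.225) and when tested against a 1.5-fold change (0.0873 and 0.136). The call of Col1a1 ended with the replicate number as a block too (0.0608).

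Neither line had appreciable Kit mRNA, and both expressed progenitor markers. Kit, the receptor that defines mature interstitial cells of Cajal (chromosome 5, 75574987 to 75656721, mm10), had 0 counts in both 2xSCS2F10 libraries, and in 2xSCS70 the only count was a single fragment in replicate 2. All 4 libraries were thus under the floor of 3 fragments, which stood at 0.109 to 0.157 CPM. The stem cell antigen Cd34 (chromosome 1, 194938821 to 194961292) was 3.83-fold higher in 2xSCS70, at 283 ± 20.9 against 73.9 ± 34.4 CPM (log2 1.94, SE 0.34, adjusted p = 0.012). The hyaluronan receptor Cd44 was 2.19-fold higher (246 ± 0.83 against 112 ± 20.4 CPM, SE 0.16, adjusted p = 0.0069). Igf1r, the receptor of insulin-like growth factors, was 1.48-fold lower (105 ± 5.70 against 155 ± 5.74 CPM, SE 0.12, adjusted p = 0.0174). The insulin receptor Insr (66.9 ± 14.4 CPM in 2xSCS2F10 and 64.7 ± 0.052 in 2xSCS70, adjusted p = 0.839) and the platelet-derived growth factor receptor Pdgfra (43.6 ± 21.4 and 31.3 ± 2.73 CPM, adjusted p = 0.32) did not pass the test. With 2xSCS2F10 replicate 1 left out both passed as lower (log2 -0.27 and -0.92, adjusted p = 0.0359 and 2.45e-09), and with its replicate 2 left out both signs turned (0.19 and 0.13). Of the 5 tested progenitor markers, 2 rose and 1 fell over all genes and also adjusted over the list alone (camera adjusted p = 0.766). The calls of Cd34, Cd44 and Igf1r ended without 2xSCS70 replicate 1 (adjusted p 0.0971, 0.0855 and 0.158) and without replicate 2 (0.0864, 0.0853 and 0.208). The call of Igf1r also ended on log2(RPKM + 1) values (0.27) and when tested against a 1.5-fold change (0.608).

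In the test on all 4 libraries, the pacemaking genes that passed were lower in 2xSCS70. Ano1, the calcium-activated chloride channel of interstitial cells of Cajal (chromosome 7, 144588549 to 144738592), was 9.96-fold lower in 2xSCS70, at 2.42 ± 0.186 against 24.1 ± 8.08 CPM (log2 -3.32, SE 0.30, adjusted p = 0.00219). The inositol trisphosphate receptor Itpr1 was 2.61-fold lower (57.4 ± 2.85 against 150 ± 8.08 CPM, SE 0.12, adjusted p = 0.00194) and the gap junction protein Gja1 was 1.46-fold lower (96.5 ± 3.81 against 141 ± 11 CPM, SE 0.12, adjusted p = 0.0228). The transcription factor Etv1 was at 0.209 ± 0.223 CPM in 2xSCS2F10 and 0.663 ± 0.167 CPM in 2xSCS70 (adjusted p = 0.16). It passed as higher without 2xSCS2F10 replicate 2 (log2 3.61, adjusted p = 0.000644) and on log2(RPKM + 0.1) values (0.043). The ligand of Kit, Kitl, was at 75.3 ± 21.6 and 73.7 ± 11.6 CPM (log2 -0.03, SE 0.24, adjusted p = 0.922). The signs of Kitl and Insr turned under upper quartile scaling (log2 0.06 and 0.04) and on log2(RPKM + 1) values (0.20 and 0.17). Kitl passed as higher without 2xSCS2F10 replicate 1 (log2 0.28, adjusted p = 0.0418) and as lower without its replicate 2 (-0.30, 0.0254). Of the 7 tested members of the identity and pacemaking list, 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.433). The calls of Itpr1 and Gja1 ended without 2xSCS70 replicate 1 (adjusted p 0.0571 and 0.225) and without replicate 2 (0.0506 and 0.184), while that of Ano1 remained, the only list member passing as lower in either case. When 2xSCS2F10 replicate 1 was left out 2 members passed as higher and 3 as lower, and 2 and 4 when its replicate 2 was. Gja1 also missed the threshold on log2(RPKM + 1) and log2(RPKM + 0.1) values (0.281 and 0.288) and when tested against a 1.5-fold change (0.699).

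**Figure D1:**
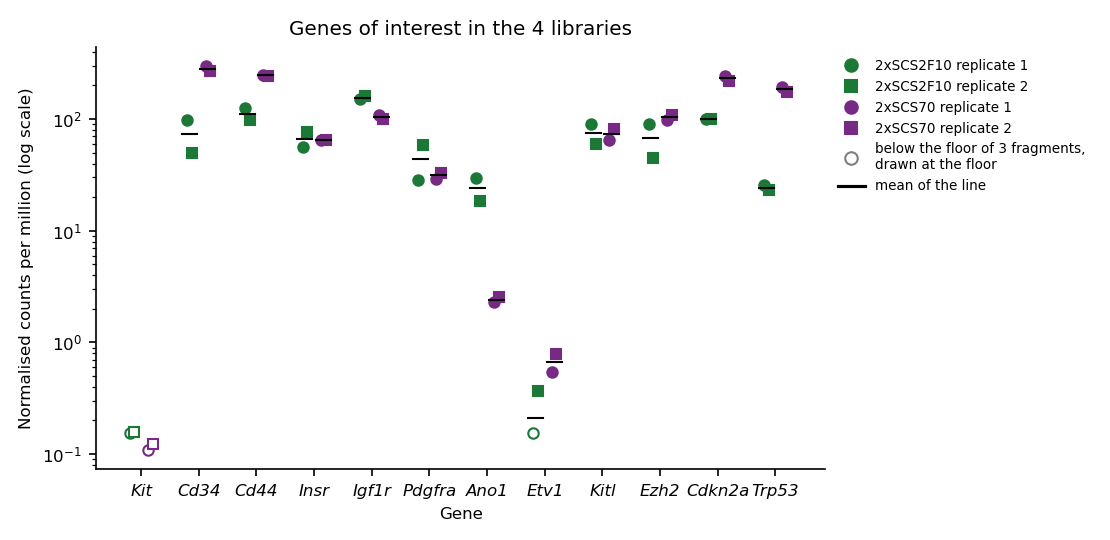
CPM values (log axis) of the 12 genes chosen in advance, with 1 point per library and a line at the mean of each cell line. Kit lay under the floor of 3 fragments in all 4 libraries, and Trp53 stood at 184 CPM in 2xSCS70 against 24.4 CPM in 2xSCS2F10.

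The comparison of the lines asked how the 2 transcriptomes differ. Of 14496 tested genes, 5888 (40.6%) changed, 2727 of them higher and 3161 lower in 2xSCS70, and 1717 and 1923 of these differed by 2-fold or more. Among the genes most strongly lower in 2xSCS70, Gabra4, a GABA receptor subunit, was at 22.9 ± 1.30 CPM in 2xSCS2F10 and had 0 counts in 2xSCS70, at least 197-fold lower. The imprinted noncoding RNAs Rian and Meg3 were 2509-fold and 1971-fold lower, the complement regulator Cd55 2405-fold, the membrane glycoprotein Gpm6a 1686-fold, the X inactivation RNA Xist 1369-fold and the complement protease C1s 1086-fold (0.332 ± 0.111 against 360 ± 206 CPM). Pkhd1l1 (3 fragments in 2xSCS70) was lower by a ratio of 2403 (95% interval 822 to 11650), Srpx (3 fragments) by 1746 (597 to 8470) and Hmgcll1 (2 fragments), an enzyme of ketone body formation, by 1124 (311 to 9291). Among the genes most strongly higher, the adhesion molecule Cadm1 was at 61.9 ± 3.0 CPM in 2xSCS70 and had 0 counts in 2xSCS2F10, at least 397-fold higher, and the ubiquitin ligase Peli2 was at least 134-fold higher. Neuronal nitric oxide synthase Nos1 (1 fragment in 2xSCS2F10) was higher by a ratio of 1135 (95% interval 203 to 44860), the monooxygenase Fmo1 (1 fragment) by 1025 (184 to 40520), the gelatinase Mmp9 (3 fragments) by 498 (170 to 2417) and the phospholipase Plcg2 (2 fragments) by 390 (108 to 3225). Adamtsl3 was 656-fold and the neutrophil chemokine Cxcl5 209-fold higher, and the Y-linked Eif2s3y and Ddx3y are described with the sex chromosomes. The adjusted p of these 20 genes lay between 0.000347 and 0.00249. Intervals and floors cover counting error only. When 2xSCS70 replicate 1 was left out the fold became 3870 for Rian, 3330 for Meg3, 5960 for Gpm6a and 1160 for Cd55, and 0 counts were left in 2xSCS70 for Pkhd1l1, Srpx and Hmgcll1. When its replicate 2 was left out Gpm6a stood at 1020, Pkhd1l1 at 1280, Srpx at 929 and Hmgcll1 at 596, with 0 counts left for Cd55. Leaving out 2xSCS2F10 replicate 1 gave 565 for Nos1, 510 for Fmo1, 406 for Adamtsl3 and 104 for Cxcl5, with 0 counts left in 2xSCS2F10 for Plcg2. Leaving out its replicate 2 gave 652 for C1s, 1610 for Adamtsl3 and 197 for Plcg2, with 0 counts left for Nos1, Fmo1 and Cxcl5.

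The number of calls depended on which spread entered the test. Without 2xSCS70 replicate 1, 850 genes changed (291 higher, 559 lower), and without its replicate 2, 889 changed (316 higher, 573 lower), since the spread then came from the more variable 2xSCS2F10 pair alone. Without 2xSCS2F10 replicate 1 the count was 9567 and without its replicate 2 it was 8957. The share of higher genes was 46.3%, against 63.8% on log2(RPKM + 1) values (3218 higher, 1828 lower) and 63.2% with a pseudocount of 0.1. The median log2 fold change of all tested genes was 0.02, and it moved to 0.11 under upper quartile scaling. It moved to 0.15 on log2(RPKM + 1) values and to 0.25 on log2(RPKM + 0.1) values. RPKM values lacked the TMM factors. Their denominators were 50468212 and 59036269 reads for 2xSCS2F10 and 62928743 and 61554553 for 2xSCS70. Library sizes after TMM scaling were 38933265 and 38106359, and 55126034 and 48663010. RPKM values thus stood higher in 2xSCS70, relative to 2xSCS2F10, than TMM-scaled CPM did. This bears on calls, signs and detection counts from RPKM. In a simulation on 14423 genes the same test recovered 2.1% of 1.5-fold, 22.9% of 2-fold, 96% of 4-fold and 100% of 8-fold changes, and it called 3 of 14227 unchanged genes. The simulation gave all genes and both lines the same spread. These rates may not carry over to the real libraries, where 40.6% of genes were called and the lines differed in spread.

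Contractile smooth muscle genes were lower in 2xSCS70 as a group. Tagln, an actin-binding protein of smooth muscle, was 59.3-fold lower (34.6 ± 0.001 against 2053 ± 889 CPM, log2 -5.89, SE 0.39, adjusted p = 0.00103), and its counts overlap the less abundant gene Pcsk7. Calponin Cnn1 was 644-fold lower (0.343 ± 0.079 against 224 ± 51.2 CPM, SE 0.31, adjusted p = 0.000347), myosin light chain Myl9 537-fold (354-fold without 2xSCS2F10 replicate 2, SE 0.58, adjusted p = 0.000962) and enteric actin Actg2 38.3-fold (SE 0.30, adjusted p = 0.000721). Of 16 tested members, 14 fell and 1 rose, over all genes and adjusted over the list alone, with a median log2 fold change of -2.54. The camera adjusted p was 7.23e-05 with the preset correlation, and adjusted p = 0.707 with an estimated correlation. In 2xSCS2F10 the median of these genes was 0.79 higher on the log2 scale in replicate 2 than in replicate 1. The lower members past the threshold numbered 5 without 2xSCS70 replicate 1 and 5 without its replicate 2.

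Mesothelial genes and the keratins Krt7, Krt8 and Krt19 were expressed in 2xSCS2F10 and lower in 2xSCS70. Upk3b, a mesothelial membrane protein, was 263-fold lower (4.61 ± 1.28 against 1214 ± 12.8 CPM, log2 -8.04, SE 0.28, adjusted p = 0.000347). Mesothelin Msln (37.6-fold), the tetraspanin-like Upk1b (16.7-fold) and the transcription factor Wt1 (17.9-fold) were lower with the same adjusted p. All 8 tested members of the mesothelial list fell, over all genes and adjusted over the list alone (camera adjusted p = 4.95e-06). With an estimated correlation the list had an adjusted p = 0.707. In the epithelial list the keratins Krt7 (433-fold, adjusted p = 0.0007), Krt8 (13-fold, adjusted p = 0.000735) and Krt19 (218-fold, 0.489 ± 0.284 against 109 ± 81.9 CPM, SE 0.85, adjusted p = 0.00349), which mesothelium also expresses, and E-cadherin Cdh1 (33.0-fold, adjusted p = 0.00223) fell. Of 7 tested epithelial members 4 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.343). Krt19 belonged to both lists and was not called without 2xSCS70 replicate 2 (adjusted p = 0.0535). Its fold was 102 without 2xSCS2F10 replicate 1, 332 without its replicate 2 and 373 without 2xSCS70 replicate 1.

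Matrix genes were mostly lower in 2xSCS70, with single genes strongly higher. The elastic fibre protein Fbln5 was 12.2-fold lower (44.9 ± 2.88 against 550 ± 26.5 CPM, SE 0.14, adjusted p = 0.000399), the basement membrane linker Nid1 51.7-fold (SE 0.27, adjusted p = 0.000524) and osteopontin Spp1 6.88-fold (SE 0.17, adjusted p = 0.000889). Periostin Postn was 65.7-fold higher (1154 ± 12.6 against 17.6 ± 3.98 CPM, SE 0.23, adjusted p = 0.000407). Of 30 tested members 18 fell and 4 rose, and 19 fell and 4 rose adjusted over the list alone. The camera adjusted p was 0.00208, and adjusted p = 0.707 with an estimated correlation. In 2xSCS2F10 the median of the list was 0.49 higher on the log2 scale in replicate 2 than in replicate 1. Without 2xSCS70 replicate 1 or without replicate 2, 5 members passed as lower and 1 as higher.

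Markers of other cell types moved in both directions. Among markers of PDGFRA-positive interstitial cells, the pericyte receptor Pdgfrb was 4.47-fold higher in 2xSCS70 (151 ± 1.85 against 33.8 ± 6.20 CPM, adjusted p = 0.00149) and the surface antigen Ly6a 17.7-fold higher (4.64 ± 0.763 against 0.258 ± 0.216 CPM, adjusted p = 0.00681). The adhesion receptor Cxadr was 2.31-fold lower (235 ± 0.618 against 545 ± 20.5 CPM, adjusted p = 0.00261). Of 7 tested members, with Cd34 among them, 3 rose and 1 fell, and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.541). Of 9 tested enteric neuron genes, 4 rose and 3 fell, and 5 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.472). They went from Nos1 through Syp, a synaptic vesicle protein higher by a ratio of 10.9 (3 fragments in 2xSCS2F10, 95% interval 3.49 to 54.8), to the ubiquitin hydrolase Uchl1, 18.9-fold lower (14.1 ± 3.69 against 267 ± 16.7 CPM, adjusted p = 0.000688). The calcium sensor Syt1 was lower by a ratio of 94.3 (2 fragments in 2xSCS70, 25.6 to 786). Of 7 tested glial genes, 1 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.766). Myelin basic protein Mbp was 2.40-fold lower (adjusted p = 0.00946), the neuregulin receptor Erbb3 7.37-fold lower (adjusted p = 0.0326), and S100b was higher by a ratio of 6.68 (3 fragments in 2xSCS2F10, 2.06 to 34.4). The calls of Ly6a, Cxadr, Syp, Mbp, Erbb3 and S100b ended without 2xSCS70 replicate 1 (adjusted p 0.0675 to 0.146) and without replicate 2 (0.076 to 0.177), and that of Erbb3 on log2(RPKM + 1) values (0.0681). Without 1 library the fold was 42.7 (2xSCS2F10 replicate 1) or 11.2 (its replicate 2) for Ly6a, and 4.23 (2xSCS2F10 replicate 1), 15.9 or 4.87 (2xSCS70 replicates 1 and 2) for Erbb3. The ratio of Syp was 16.4 with 2xSCS2F10 replicate 1 left out, and that of S100b 10.1 with its replicate 2 left out. Without either 2xSCS70 library 1 neuronal gene passed as higher and 2 as lower.

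The named endothelial and leukocyte markers were under 5 CPM in both lines, and striated muscle markers moved in both directions. Egfl7 was 4.94-fold higher (2.32 ± 0.15 against 0.467 ± 0.066 CPM, adjusted p = 0.00681) and VE-cadherin Cdh5 at least 3.01-fold higher in 2xSCS70, while the receptor Tek was 6.13-fold and the transcription factor Erg 3.35-fold lower. Of 7 tested endothelial genes 2 rose and 2 fell, likewise adjusted over the list alone (camera adjusted p = 0.783). Of 6 tested leukocyte genes 2 rose, likewise adjusted over the list alone (camera adjusted p = 0.276): lysozyme Lyz2 (1.76 ± 0.646 against 0.156 ± 0.002 CPM, adjusted p = 0.00661) and the lysosomal protein Cd68 (3.4 ± 0.708 against 1.64 ± 0.135 CPM, adjusted p = 0.0407). Of 6 tested genes of skeletal and cardiac muscle 1 rose and 3 fell, likewise adjusted over the list alone (camera adjusted p = 0.259). Cardiac troponin Tnnt2 was 23.5-fold higher (117 ± 4.80 against 4.96 ± 0.406 CPM, adjusted p = 0.000347), and the transcription factors Gata6 (4.04-fold), Gata4 (55.2-fold) and Pax3 (15.8-fold) were lower. The calls of Egfl7, Tek, Cdh5, Erg and Cd68 ended without 2xSCS70 replicate 1 (adjusted p 0.0814 to 0.206), and these and that of Lyz2 without replicate 2 (0.0701 to 0.3). The fold of Gata4 was 33 without 2xSCS70 replicate 1 and 141 without its replicate 2. Cdh5 missed the threshold on log2(RPKM + 1) values (0.0637). Erg and Cd68 missed it with the replicate number as a block (0.0514 and 0.058) and when tested against a 1.5-fold change (0.0649 and 0.143).

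Hox genes, which set position along the body axis, were higher in 2xSCS70 as a group, with members moving in both directions. Hoxb13 was higher by a ratio of 670 (1 fragment in 2xSCS2F10, 95% interval 120 to 26500; 17.3 ± 1.94 CPM in 2xSCS70), Hoxc13 by 102 (2 fragments, 28.0 to 847), and Hoxd9 was at least 80.1-fold higher (12.5 ± 1.38 CPM). Hoxa5 was 14.0-fold lower (1.38 ± 0.151 against 19.3 ± 0.844 CPM, adjusted p = 0.000648), and its coordinates overlap those of Hoxa3. Of 30 tested members 19 rose and 4 fell, and 19 rose and 5 fell adjusted over the list alone. The median log2 fold change was 4.06, or 2.10 with the 8 members at 0 counts in a line set to their bound. The camera adjusted p was 0.000116, and adjusted p = 0.707 with an estimated correlation. Without 2xSCS70 replicate 1, 9 members passed as higher and 1 as lower, and without replicate 2, 10 and 1. The ratio of Hoxb13 was 337 without 2xSCS2F10 replicate 2, and without its replicate 1 the gene had 0 counts left in that line.

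Regulators of mesenchymal differentiation split between the lines. Twist2 was 82.9-fold higher in 2xSCS70 (13.1 ± 2.80 against 0.155 ± 0.145 CPM, adjusted p = 0.00216) and the bone regulator Runx2, which overlaps Supt3h, 1.97-fold higher (adjusted p = 0.00787). Prrx2 was lower by a ratio of 210 (2 fragments in 2xSCS70, 95% interval 57.5 to 1738). The fat cell regulator Pparg, at 4.93 and 2.36 CPM in replicates 1 and 2 of 2xSCS2F10, was at least 31.4-fold lower on their mean. Of 23 tested members 9 rose and 5 fell, likewise adjusted over the list alone (camera adjusted p = 0.766). The list had a median log2 fold change of 0.04, a mean of -0.48 and an upward camera direction. Among targets of the Hedgehog, Wnt and Notch pathways, Notch1 was 8.80-fold higher (adjusted p = 0.00421), while the secreted Dkk3 was 35.4-fold, the Hedgehog co-receptor Cdon 2.67-fold and the Notch target Hey2 at least 29.5-fold lower. Of 22 tested members 10 rose and 5 fell, likewise adjusted over the list alone (camera adjusted p = 0.406). In the retinoic acid list the synthesizing enzymes Aldh1a1 (168-fold, 2.65 ± 0.151 against 444 ± 5.38 CPM, adjusted p = 0.000347) and Aldh1a2 (a ratio of 609, 1 fragment in 2xSCS70, 109 to 24100) and transglutaminase Tgm2 (117-fold) were lower, and the degrading enzyme Cyp26b1 was 5.71-fold higher (adjusted p = 0.0084). Of 12 tested members 3 rose and 6 fell, likewise adjusted over the list alone (camera adjusted p = 0.294), but camera called the list lower with a filter at a mean of 5 CPM (adjusted p = 0.0211) and on halved counts (0.029). The calls of Runx2, Cdon, Notch1, Aldh1a2 and Cyp26b1 ended without 2xSCS70 replicate 1 (adjusted p 0.0608 to 0.0968) and without replicate 2 (0.0567 to 0.0987). Leaving out 2xSCS2F10 replicate 1 moved Twist2 to 236-fold and Prrx2 to a ratio of 136, and leaving out its replicate 2 moved Twist2 to 50.5-fold and Aldh1a2 to a ratio of 255. Aldh1a2 stood at 287 without 2xSCS70 replicate 1 and had 0 counts left in 2xSCS70 without replicate 2. Without replicate 1 of 2xSCS70, 1 mesenchymal gene passed as higher and 3 as lower (1 and 2 without replicate 2), and without either of its replicates 2 pathway targets and 2 retinoic acid genes passed, all lower.

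DNA replication genes were higher as a group in 2xSCS70 at the preset correlation, to a degree that differed between the 2xSCS2F10 libraries. Mitotic genes differed more between those libraries than between the lines. The X-linked Pola1, the catalytic subunit of DNA polymerase alpha, was 4.38-fold higher (130 ± 6.78 against 29.6 ± 9.24 CPM, SE 0.24, adjusted p = 0.00387). The helicase subunits Mcm3 and Mcm6 were 3.32-fold and 2.30-fold higher (adjusted p = 0.00884 and 0.0043), and the uracil glycosylase Ung 3.56-fold (adjusted p = 0.00751). Genes of X, and of chromosome 1, which holds Mcm3 and Mcm6, were higher as groups in 2xSCS70, as described with the chromosomes. Of 26 tested S phase genes 10 rose, and 9 adjusted over the list alone, with a camera adjusted p = 0.000218 that became an adjusted p = 0.707 with an estimated correlation. Topoisomerase Top2a was at 609 ± 20.2 CPM in 2xSCS70 and 265 ± 226 CPM in 2xSCS2F10 (adjusted p = 0.185), and Ube2c, a ubiquitin conjugase of mitosis, at 79.3 ± 2.01 and 63.1 ± 60.5 CPM (adjusted p = 0.736). Of 28 tested G2/M genes edgeR called 0, over all genes and adjusted over the list alone, with 1 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. The camera test of that list gave an upward adjusted p = 0.0189, and adjusted p = 0.778 with an estimated correlation. In 2xSCS2F10 replicate 2 all 28 G2/M genes and all 26 S phase genes were lower than in replicate 1, by medians of -2.08 and -0.89 on the log2 scale. Against 2xSCS2F10 replicate 1 the median G2/M difference of 2xSCS70 was 0.16, and against replicate 2 it was 2.30. For the S phase list these differences were 0.57 and 1.71. The fry test did not call the S phase list (adjusted p = 0.163). Without 2xSCS2F10 replicate 1 all 28 G2/M and 26 S phase genes passed as higher. Without 2xSCS2F10 replicate 2, 12 G2/M genes passed as higher and 4 as lower, 19 S phase genes as higher, and the G2/M list was not called (camera adjusted p = 0.339). Ube2c passed as higher in the former case (log2 1.95, adjusted p = 1.48e-18) and as lower in the latter (-0.42, 0.000987), and Top2a as higher in both (2.52 and 0.52, adjusted p = 1.58e-24 and 3.45e-05). With either 2xSCS70 library left out edgeR called 0 of the 26 S phase genes, with 7 at an unadjusted p under 0.05, whereas on all libraries DESeq2 called 18 and limma-voom 13. Pola1, Mcm3, Mcm6 and Ung missed the threshold without 2xSCS70 replicate 1 (adjusted p 0.0515 to 0.0845) and without replicate 2 (0.0552 to 0.0802).

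**Figure D2:**
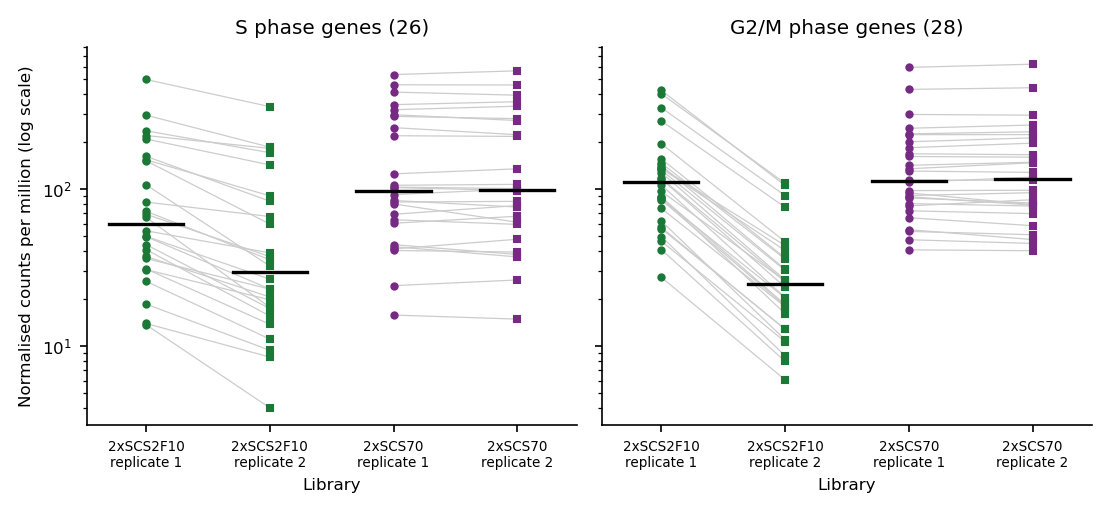
CPM values (log axis) of the 26 tested S phase genes and 28 tested G2/M genes in the 4 libraries, with grey lines joining the replicates of a line and a black bar at the median. The G2/M median was 111 CPM in 2xSCS2F10 replicate 1 and 24.8 CPM in replicate 2, against 112 and 116 CPM in 2xSCS70.

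The tumour suppressors Trp53 and Cdkn2a were higher in 2xSCS70, and genes of the p53 pathway moved both ways. Trp53 (chromosome 11, 69580359 to 69591873) was 7.55-fold higher, at 184 ± 15.2 against 24.4 ± 1.69 CPM (log2 2.92, SE 0.14, adjusted p = 0.000515). The 50 tested genes nearest to it, from 68968131 to 69916591, had a median log2 fold change of 0.69, with 23 of them higher and 2 lower. Cdkn2a, which encodes p16 and p19ARF, was 2.30-fold higher (232 ± 17.9 against 101 ± 0.088 CPM, SE 0.12, adjusted p = 0.00275). The cell cycle inhibitor and p53 target Cdkn1a was 3.39-fold lower (58.2 ± 3.78 against 197 ± 13.1 CPM, SE 0.13, adjusted p = 0.00121) and the p53 target Perp 18.1-fold lower (adjusted p = 0.00049), whereas the noncoding RNA Pvt1 was 3.25-fold higher (adjusted p = 0.00193). Of 30 tested p53 pathway genes 9 rose and 9 fell, likewise adjusted over the list alone (camera adjusted p = 0.766). Among immortalization genes, cyclin D2 Ccnd2 was 22.8-fold lower (39.5 ± 4.89 against 900 ± 109 CPM, adjusted p = 0.000456) and cyclin D3 Ccnd3, which overlaps Bysl, 3.64-fold lower. Of 28 tested members 6 rose and 10 fell, and 7 rose and 11 fell adjusted over the list alone (camera adjusted p = 0.433). The call of Cdkn2a ended without 2xSCS70 replicate 1 (adjusted p = 0.0617) and without replicate 2 (0.0503). Without the one or the other of these libraries 1 member passed as higher and 3 as lower in the p53 list, and 1 and 5 in the immortalization list.

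Genes of the interferon response and of MHC class I were higher in 2xSCS70, although interferon gamma was left out of its medium. The immunoproteasome subunit Psmb8 was 23.9-fold higher (19.9 ± 0.208 against 0.831 ± 0.086 CPM, SE 0.21, adjusted p = 0.00049), the MHC class I gene H2-D1 9.02-fold (115 ± 12.3 against 12.8 ± 0.65 CPM, SE 0.15, adjusted p = 0.000506) and the guanylate-binding protein Gbp3 10.6-fold (adjusted p = 0.00102). The antiviral protein Rsad2 had 0 counts in 2xSCS2F10 and was at least 38.1-fold higher (5.93 ± 0.486 CPM, adjusted p = 0.00161). Of 37 tested members 27 rose, and 28 adjusted over the list alone, with a median log2 fold change of 1.94. The camera adjusted p was 3.41e-08, and adjusted p = 0.707 with an estimated correlation. Reads of H2-D1 may be shared with other class I genes. Without 2xSCS70 replicate 1, 9 members passed as higher, and without replicate 2, 10.

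More cytokine genes fell than rose in 2xSCS70. The alarmin Il33 was 14.6-fold lower (3.39 ± 0.435 against 49.5 ± 2.08 CPM, SE 0.17, adjusted p = 0.000485), fibroblast growth factor Fgf2 24-fold (adjusted p = 0.00108), the angiogenic factor Vegfa 9.14-fold (43.7 ± 6.18 against 399 ± 49.97 CPM, SE 0.18, adjusted p = 0.0007) and the macrophage growth factor Csf1 3.29-fold (370 ± 31.1 against 1215 ± 21.9 CPM, SE 0.14, adjusted p = 0.00172). Of 31 tested members 13 fell and 4 rose, Cxcl5 among the latter, likewise adjusted over the list alone. The camera adjusted p was 0.0151, and adjusted p = 0.707 with an estimated correlation. The list was not called without 2xSCS2F10 replicate 2 (camera adjusted p = 0.158) or with a filter at a mean of 5 CPM (0.113). Without 2xSCS70 replicate 1 or without replicate 2, 4 members passed as lower and 1 as higher, and Csf1 missed the threshold (adjusted p 0.0571 and 0.0643). The median log2 difference of the list was -0.56 against 2xSCS2F10 replicate 1 and -1.28 against its replicate 2.

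Stress genes were lower as groups in 2xSCS70, the line kept at 39.5 °C. Among heat shock genes the small chaperones Hspb8 (4.0-fold, 25.2 ± 1.15 against 101 ± 2.25 CPM, SE 0.12, adjusted p = 0.000835), Cryab (5.26-fold, SE 0.17, adjusted p = 0.00121) and Hspb1 (88.7-fold, 2.74 ± 0.386 against 243 ± 188 CPM, SE 0.72, adjusted p = 0.00371) and the co-chaperone Dnajb4 (2.04-fold, adjusted p = 0.0042) fell. Of 22 tested members 8 fell and 1 rose, likewise adjusted over the list alone (camera adjusted p = 0.0088). With an estimated correlation the heat shock list had an adjusted p = 0.707. In the unfolded protein response list, Chac1 (4.87-fold, adjusted p = 0.000976) and Trib3 (8.47-fold, adjusted p = 0.00155), both targets of the stress factor ATF4, asparagine synthetase Asns (2.54-fold, adjusted p = 0.00177) and Herpud1 (3.13-fold, adjusted p = 0.00199) fell. Of 20 tested members 13 fell, likewise adjusted over the list alone (camera adjusted p = 0.000235, and adjusted p = 0.707 with an estimated correlation). Dnajb4 (log2 -1.03) lies in a window of 50 neighbouring genes on chromosome 3 with a median log2 fold change of -0.78. Asns (log2 -1.34) lies in such windows on chromosome 6 with medians of -0.74 and -0.71. The changes of these genes may therefore be partly those of their neighbourhood. The fold of Hspb1 was 138 without 2xSCS2F10 replicate 1 and 40.1 without its replicate 2. Hspb1, Dnajb4 and Asns lost their calls without 2xSCS70 replicate 1 (adjusted p 0.0599 to 0.0868), and these and Herpud1 without replicate 2 (0.0504 to 0.0787). The members past the threshold as lower then numbered 2 and 2 for heat shock and 3 and 2 for the unfolded protein response, while without 2xSCS2F10 replicate 1 and without replicate 2 of that line 18 and 14 heat shock genes passed as lower.

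Genes of cholesterol synthesis were lower as a group in 2xSCS70, and those of glycolysis and the immediate early response moved both ways. The sterol oxidase Sc4mol was 2.92-fold lower (237 ± 4.38 against 691 ± 125 CPM, SE 0.17, adjusted p = 0.00349) and squalene synthase Fdft1, which overlaps Ctsb, 2.10-fold lower (adjusted p = 0.00414), while the X-linked Nsdhl was 2.29-fold higher (adjusted p = 0.0051). Sc4mol lies in a window of 50 neighbouring genes on chromosome 8 with a median log2 fold change of -0.64. Of 25 tested members 8 fell and 2 rose, likewise adjusted over the list alone (camera adjusted p = 0.0231, and adjusted p = 0.777 with an estimated correlation). All 25 were lower in replicate 2 than in replicate 1 of 2xSCS2F10, by a median of -0.52 on the log2 scale, and the list was not called without replicate 1 of that line (camera adjusted p = 0.11). Without its replicate 2, 21 members passed as lower. In the glycolysis and hypoxia list Aldoc (25.8-fold, 1.04 ± 0.426 against 27.1 ± 19.4 CPM, adjusted p = 0.00731) and the oxygen sensor Egln3 (3.57-fold, adjusted p = 0.00816) were lower, like Vegfa, and the X-linked Pgk1 was 1.85-fold higher (adjusted p = 0.00659). Of 26 tested members 7 fell and 2 rose, and 5 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.276). The median log2 difference of this list was -0.12 against 2xSCS2F10 replicate 1 and -0.63 against its replicate 2. Of 29 tested immediate early and YAP or TGF-beta target genes 6 rose and 11 fell, likewise adjusted over the list alone (camera adjusted p = 0.406). Ankrd1, a YAP target, was 9.36-fold higher (107 ± 7.72 against 11.5 ± 2.63 CPM, adjusted p = 0.000967), and the phosphatase Dusp1 (4.79-fold), Ier3 (5.87-fold) and the ERK pathway inhibitor Spry4 (10.3-fold) were lower. The fold of Aldoc was 39 without 2xSCS2F10 replicate 1 and 12.7 without its replicate 2. The calls of Sc4mol, Fdft1, Nsdhl, Pgk1, Aldoc and Egln3 ended without 2xSCS70 replicate 1 (adjusted p 0.0699 to 0.11) and without replicate 2 (0.0719 to 0.109). Fewer members of the cholesterol, glycolysis and immediate early lists then passed, in either direction. The median log2 difference of the immediate early list was -0.55 against 2xSCS2F10 replicate 1 and -0.10 against its replicate 2.

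Imprinted genes were lower in 2xSCS70 as a group. The maternally expressed RNAs Rian (0.189 ± 0.092 against 488 ± 110 CPM, SE 0.39, adjusted p = 0.000347) and Meg3 (0.207 ± 0.118 against 421 ± 35.2 CPM, SE 0.35, adjusted p = 0.000347) lie side by side on chromosome 12, at 109603945 to 109661711 and 109540996 to 109571729. The growth factor adaptor Grb10 was 7.89-fold (adjusted p = 0.000474) and the zinc finger gene Peg3 6.64-fold lower (adjusted p = 0.000485). Of 21 tested members 14 fell and 2 rose, likewise adjusted over the list alone. The camera adjusted p was 0.00293, and adjusted p = 0.707 with an estimated correlation. The members past the threshold numbered 9 lower and 1 higher without 2xSCS70 replicate 1, and the same numbers without its replicate 2. Of 27 tested Polycomb and DNA methylation genes 8 rose and 5 fell, and 9 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.259). The Polycomb reader Cbx7 was at least 34.1-fold higher, the core subunit Eed 1.91-fold (adjusted p = 0.0052), the demethylase Kdm6b 2.45-fold (adjusted p = 0.00643) and the methyltransferase Dnmt3b 4.13-fold (adjusted p = 0.00738). Kdm6b lies within the stretch of chromosome 11 around Trp53 that had a median log2 fold change of 0.69. The H3K27 methyltransferase Ezh2 stood at 104 ± 7.03 CPM in 2xSCS70 and 67.7 ± 31.8 CPM in 2xSCS2F10 and did not pass (adjusted p = 0.194), but did without 2xSCS2F10 replicate 1 (log2 1.19, adjusted p = 3.39e-12). The calls of Eed, Kdm6b and Dnmt3b ended without 2xSCS70 replicate 1 (adjusted p 0.0841 to 0.0852) and without replicate 2 (0.0605 to 0.0894). Without replicate 1 or without replicate 2 of 2xSCS2F10, 15 Polycomb and DNA methylation genes passed as higher and 7 as lower, and 1 as higher without either replicate of 2xSCS70.

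Sex-linked transcripts separated the lines. Xist, the noncoding RNA of the inactive X chromosome, was at 1701 ± 133 CPM in 2xSCS2F10 and 1.23 ± 0.464 CPM in 2xSCS70 (log2 -10.42, SE 0.36, adjusted p = 0.000347). The Y-linked genes Ddx3y (59.8 ± 4.42 CPM in 2xSCS70, 560-fold higher, adjusted p = 0.0004), Kdm5d (19.8 ± 1.58 CPM, 185-fold, adjusted p = 0.000659) and Eif2s3y (30.9 ± 4.27 CPM, a ratio of 591 with 2 fragments in 2xSCS2F10, 95% interval 163 to 4886) were higher in 2xSCS70. In the absence of 2xSCS2F10 replicate 1 the values were 370, 122 and 294 for Ddx3y, Kdm5d and Eif2s3y, and in that of its replicate 2 1100 and 365, with 0 counts left for Eif2s3y. Of 6 tested members of the X inactivation and Y-linked list 4 rose and 2 fell, likewise adjusted over the list alone (camera adjusted p = 0.372).

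**Figure D3:**
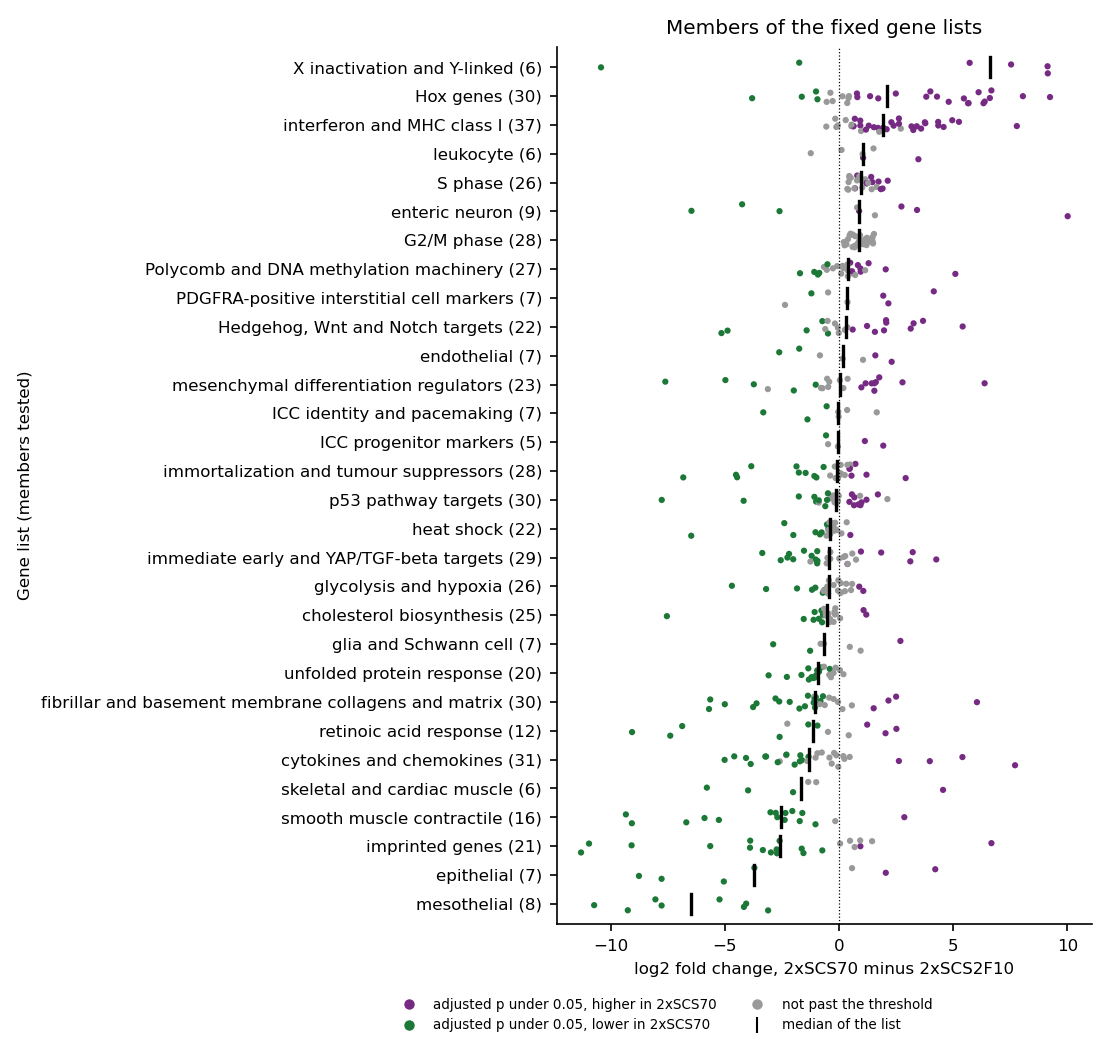
Log2 fold changes (2xSCS70 minus 2xSCS2F10) of the tested members of each gene list, ordered by median, with 1 point per gene, coloured by the edgeR call, and a black bar at the median. Genes at 0 counts in a line are drawn at their bound. The mesothelial median was -6.50 and the interferon and MHC class I median 1.94.

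Genes of several chromosomes were shifted as groups. Genes of the X chromosome were higher in 2xSCS70, with a median of 1.62-fold over 458 tested genes (log2 0.70, camera adjusted p = 1.82e-06). Of these genes 229 were higher and 67 lower. All 41 windows of 50 neighbouring genes lay above 0. Neighbouring windows shared most of their genes, so numbers of windows do not count separate stretches. Genes of chromosome 18 were lower, with a median log2 fold change of -0.46 (26 higher and 150 lower of 395, adjusted p = 4.85e-05). Chromosomes 6 (-0.35, adjusted p = 0.00115) and 17 (-0.24, 0.00666) were lower, and 12 (0.37, 0.00483), 1 (0.31, 0.00863), 7 (0.27, 0.0183) and the 7 tested genes of Y (0.0469) higher. With an estimated correlation the adjusted p of these 8 chromosomes lay between 0.159 and 0.438. Windows above 0 numbered 46 of 46 on chromosome 12 and 0 of 35 on chromosome 18, but 78 of 83 on chromosome 1, 89 of 103 on 7, 3 of 69 on 6 and 5 of 69 on 17. The highest windows were overlapping ones on chromosome 9, from 108403633 to 110856522 and from 108572313 to 113587152 (median 1.07 each). The lowest was on chromosome 6, from 13069759 to 29718558 (-0.90). Chromosome 7 was not called without 2xSCS2F10 replicate 1 (adjusted p = 0.121), and Y neither without that library (0.0784) nor without 2xSCS70 replicate 2 (0.0501). Chromosome 12 missed the threshold without a filter (0.055) and Y under upper quartile scaling (0.0561).

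**Figure D4:**
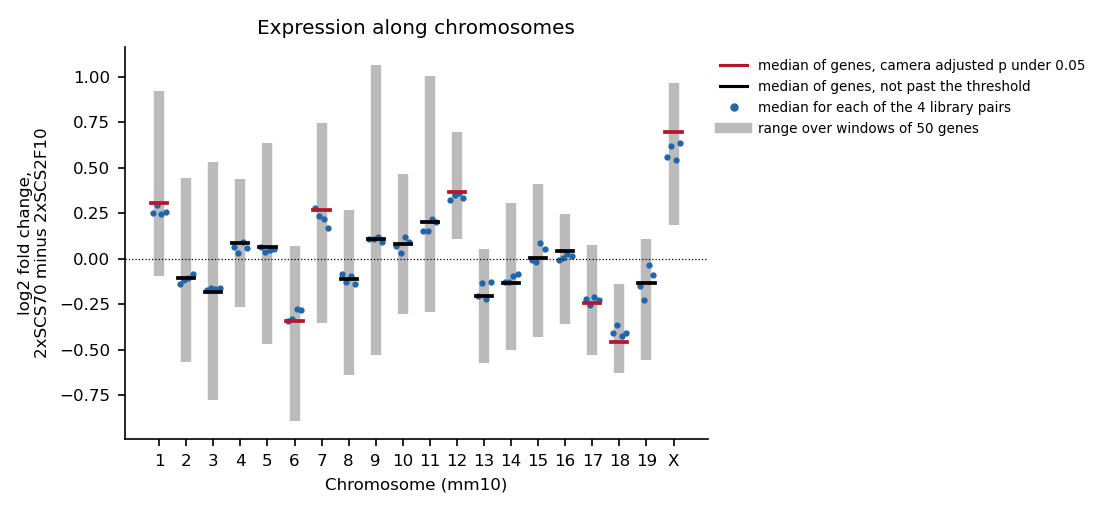
Median log2 fold change (2xSCS70 minus 2xSCS2F10) of the tested genes of each chromosome except Y, which had 7 tested genes and is not drawn, with blue points for the 4 pairs of libraries and grey bars for the range over windows of 50 neighbouring genes. Of the chromosomes drawn X stood highest, at 0.70 with pair medians of 0.54 to 0.64, and chromosome 18 lowest, at -0.46. Chromosome medians were taken over fitted changes and pair medians over differences of log2 CPM with a small constant added, so the measures differ.

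The replicate numbers, deposited apart, were also compared. Rn45s (log2 1.40, SE 0.46), Lars2 (1.61, SE 0.32) and the nuclear RNA Malat1 (0.87, SE 0.27), which was chosen after its values were seen, had higher values in the libraries numbered 2, each with an edgeR adjusted p = 0.981. Across 14496 genes edgeR called 0 genes, with 272 at an unadjusted p under 0.05, and DESeq2 called 3. These were Rn45s (1.42, adjusted p = 7.11e-09), the RNA of the RNase MRP complex Rmrp (2.18, adjusted p = 0.0346) and Krt19 (-1.57, adjusted p = 0.00655), of which Rmrp was named after its values were seen.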

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

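Of the 5888 genes called in the reported test 0 were called in the opposite direction in any alternative, and of the 125 named genes that were called 80 kept their call without each library in turn. Calls of 42 named genes ended without 2xSCS70 replicate 1 and of 45 without its replicate 2, and without a 2xSCS2F10 library 0 ended. With a 2xSCS2F10 library left out the spread came from the closer 2xSCS70 pair alone, so that calls kept there were a weak check. Most named genes were picked for large changes or small adjusted p, so their share of kept calls does not hold for all calls. Of all called genes a far smaller share was called without a 2xSCS70 library. Among the other settings, calls ended for 7 named genes when tested against a 1.5-fold change (Igf1r, Gja1, Erbb3, Erg, Cd68, Sparc and Col1a1), 6 on log2(RPKM + 1) values (Igf1r, Gja1, Erbb3, Cdh5, Sparc and Col1a1), 4 on log2(RPKM + 0.1) values (Igf1r, Gja1, Sparc and Col1a1) and 1 (Col1a1, adjusted p = 0.0507) with a filter at a mean of 5 CPM. The alternatives below were chosen after seeing the data: counts halved to fragments (5884 genes changed), Rn45s and Lars2 left out (5915), and chromosomes X and Y left out (5542). Where no reason is given below, the cause was not tested. A 2-fold change was recovered in 22.9% of simulated genes, which were drawn with the same spread for all genes and both lines.

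With the replicate number as a block, 5222 genes changed (2381 higher, 2841 lower), 5001 of them shared with the reported 5888, and the calls of Erg, Cd68 and Col1a1 ended (adjusted p 0.0514, 0.058 and 0.0608), while chromosome 13 passed (0.0468). Over genes as a whole the numbers did not pair the samples: the differences between replicates of the 2 lines had Pearson's r of 0.054 across genes and 51.5% of genes had the same sign. That does not exclude shifts shared by a few RNAs, such as Rn45s, Lars2 and Malat1, whose shares were higher in replicate 2 of both lines.

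Leaving out 1 library gave 850 to 9567 changed genes, 291 to 4772 higher and 559 to 4795 lower, and 291 to 2445 higher and 559 to 2301 lower by 2-fold or more. The low counts came from leaving out a 2xSCS70 library, which leaves the spread of the 2xSCS2F10 pair alone. A test against a 1.5-fold change, stricter by construction, called 3094 genes (1338 higher, 1756 lower). With a filter at a mean of 5 CPM, which tests fewer genes, 856 were higher and 1112 lower by 2-fold or more. On log2(RPKM + 1) values 1828 genes were lower, 924 of them by 2-fold or more, and on log2(RPKM + 0.1) values 1964. RPKM values lack the TMM factors and stand higher in 2xSCS70, relative to 2xSCS2F10, than TMM-scaled values. RLE scaling gave 5926 genes, upper quartile scaling 5947, no filter 5497, DESeq2 6326 and limma-voom 6083. Between replicate numbers DESeq2 called 3 genes where edgeR called 0.

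With an estimated correlation 0 lists were called higher and 0 lower, against 4 and 8, and 0 chromosomes against 8. A filter at a mean of 5 CPM called 13 chromosomes. Among them were chromosomes 11 (camera adjusted p = 0.0271) and 13 (0.0442), which stood at 0.0512 each in the reported test. Both also passed on halved counts (0.0318 and 0.0464), and chromosome 11 without X and Y (0.0352). Directions of lists that were not called turned for ICC identity without a filter (adjusted p = 0.981), for ICC progenitors, glia and endothelium without 2xSCS2F10 replicate 1 (0.985 each, with ranges over the libraries left out of 0.399 to 0.985, 0.683 to 0.985 and 0.734 to 0.985), for endothelium on halved counts (0.753), for mesenchymal regulators without 2xSCS70 replicate 1 (0.994, range 0.667 to 0.994), and for Hedgehog, Wnt and Notch targets at a mean of 5 CPM (0.415). For enteric neurons fry gave the downward direction (adjusted p = 0.00319) where camera gave the upward one. The fry test, which does not compare a list with other genes, missed the threshold for matrix (0.087), S phase (0.163), G2/M (0.423) and cholesterol genes (0.243), and passed it for PDGFRA-positive cell markers (0.00237), epithelial (0.00683), Polycomb (0.0409), immortalization (0.0224) and retinoic acid genes (0.0224). Chromosome 15 turned at a mean of 5 CPM (0.882) and without 2xSCS2F10 replicate 2 (0.848, range 0.693 to 0.848), and chromosome 16 under upper quartile scaling (0.994), without 2xSCS70 replicate 1 (0.996, range 0.863 to 0.996), on halved counts (0.924) and without X and Y (0.908).

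Among genes that were not called, the log2 fold change turned for Insr under upper quartile scaling (0.042), without 2xSCS2F10 replicate 2 (0.19, range -0.27 to 0.19) and on RPKM values (0.17 and 0.20). Kitl turned under upper quartile scaling (0.055), at a mean of 5 CPM (0.006), without 2xSCS2F10 replicate 1 (0.28, adjusted p = 0.0418), without 2xSCS70 replicate 1 (0.12, range -0.30 to 0.28) and on RPKM values (0.20 and 0.22). Without 2xSCS2F10 replicate 2, Pdgfra (0.13, range -0.92 to 0.13), Ube2c (-0.42, adjusted p = 0.000987, range -0.42 to 1.95) and Lars2 (0.19, range -1.86 to 0.19) turned. Eef1a1 turned on RPKM values (0.12 with either pseudocount), and Actb without 2xSCS2F10 replicate 1 (-0.12) and without 2xSCS70 replicate 2 (-0.018, range -0.12 to 0.32). Kitl and Ube2c thus passed in the turned direction without 1 library. Other genes not called in the reported test passed in its direction: Insr, Pdgfra, Ezh2, Top2a, Ube2c, Rn45s and Lars2 without 2xSCS2F10 replicate 1, Etv1, Kitl, Top2a and Actb without its replicate 2, and Etv1 on log2(RPKM + 0.1) values.

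At limits of 0.5 and 2 RPKM, 11322 and 9264 genes were detected in 2xSCS2F10 and 11649 and 9793 in 2xSCS70. Agreement within a line was 0.990 and 0.997 with a pseudocount of 0.1 CPM, and 0.982 and 0.998 over tested genes, for 2xSCS2F10 and 2xSCS70.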

Other observations

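Several of the tests below were chosen after the results they bear on had been seen. They were the escape genes, the 10 genes highest in 2xSCS2F10, the median of the leukocyte list and the leukocyte fragments. The comparisons with random lists were not in the plan fixed before the data, and they concern patterns picked for their size. Random lists do not keep the correlation between genes of a real list, so these comparisons bear on expression level and gene length only.

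Detection at 1 RPKM or more in both libraries of a line gave a view of the lists that needed no test. Of 39 Hox genes, 13 were detected in 2xSCS2F10 and 22 in 2xSCS70, and of 38 interferon and MHC class I genes 19 and 33. Of 30 imprinted genes 16 and 10 were detected, of 18 contractile smooth muscle genes 14 and 10, and of 9 mesothelial genes 8 and 5. Leukocyte markers (2 and 3 of 16), endothelial markers (1 of 12, in 2xSCS70) and glial markers (1 and 1 of 14) were mostly below that level in both lines, while all 26 S phase and 28 G2/M genes were detected in both.

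Genes of the X chromosome were higher in 2xSCS70, which carried Y-linked transcripts, than in 2xSCS2F10, which expressed Xist: the ratio of the median X RPKM to the autosomal one was 1.08 and 1.14 in the 2xSCS70 libraries and 0.758 and 0.724 in those of 2xSCS2F10. Expression level and gene length did not account for it, as the X median of 0.70 (log2) exceeded the highest of 10000 matched autosomal lists, 0.18. A further X copy in 2xSCS70 is a candidate explanation, under which genes that escape X inactivation may differ less. Of these, Kdm6a, Kdm5c, Ddx3x and Eif2s3x had a median of -0.15 against 0.70 for the other X genes, at the percentile of 11.2 among random lists of X genes. The test decided nothing, with 4 genes. It also could not tell a further copy from other causes, since escape genes are read from an inactive X in 2xSCS2F10 too, which lowers their difference whatever raised the X. Copy number was not measured, and strain, culture and a difference in sex, inferred here only from Xist and Y-linked transcripts and not given in the labels, stay open, untested.

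The G2/M genes were lower in replicate 2 than in replicate 1 of 2xSCS2F10. Expression level and gene length did not account for this, the lowest of 10000 matched random lists being -0.25 (log2) against -2.08. RNA of cells lacking the genes highest in 2xSCS2F10 diluting replicate 2 was argued against by the 10 such named genes, whose median difference was 0.17 and not near -2.08. Smooth muscle genes moved the other way, with a median of 0.79 and 1 of 16 lower in replicate 2, as did matrix genes, with 0.49 and 3 of 30 lower. RNA of cells that share those 10 genes, or a less dividing and more contractile culture of the line, may therefore remain, and density and passage were not given in the labels used here.

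Interferon and MHC class I genes were higher in 2xSCS70, whose transgene carries an H-2Kb promoter. Expression level and gene length did not account for the list's median of 1.94 (log2), the highest of 10000 matched random lists being 0.77. The leukocyte list did not decide whether leukocytes were among the 2xSCS70 cells, with a median of 1.04 without being called (camera adjusted p = 0.276). Lyz2 and Cd68 rose, to 1.76 and 3.4 CPM, and Cd68 lies in the stretch around Trp53 described above. Ptprc, Tyrobp, C1qa, C1qb, Emr1 and Itgam gave 1 fragment in all over both 2xSCS70 libraries, against 6019 of H2-D1 and 1034 of Psmb8. This argues against leukocytes that express those 6 genes as the source of the higher interferon and MHC class I values. A difference of line, strain or temperature may underlie these values, as a hypothesis that the design leaves untested.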
